A study of Mus musculus with 2 samples.

How the data were processed

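Small RNA below 30 nucleotides was sequenced from the stomachs of 2 newborn mice, per the labels. The labels describe the libraries as biological replicates 1 and 2, from different pups of 1 dam, so p-values between them compare these libraries, and spreads are those between 2 littermates. The authors deposited 1 table of raw read counts per library, with no header and no normalization. Each has a gene identifier, a count without regard to strand, and a count for each strand, for 1973 miRNA genes. The count without regard to strand equalled the sum of both strand counts for every gene. One strand column held 97.7% (exact 95% interval 97.7% to 97.8%) of gene counts in pup 1 and 97.8% in pup 2, and was taken as the gene's own strand. The description files that accompany the tables name the assembly mm10 and the annotation release M4. The aligner, the counting tool and the treatment of adapters are not given in the sources used here.

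Reads that named no gene stayed out of library totals. Of 7194298 reads in the table of pup 1, 8.70% were unmapped, 26.0% mapped to several places and 1.78% fell outside annotated miRNA genes, while 0 were ambiguous. Of 5546207 reads of pup 2, the shares were 8.94%, 25.7% and 1.70%, again with 0 ambiguous. Own-strand counts summed to 4463355 and 3454655. Reads from a mature miRNA that several genes encode can fall among those mapping to several places, which lowers the counts of such genes. PCR reads without molecular identifiers are not independent molecules, so every interval and floor covers counting error only.

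Gene names, positions and host genes came from GENCODE release M21 on GRCm38, the assembly that mm10 names. Of the 1973 identifiers 1894 matched without their version, 1815 of them with the same version, and the other 79 held 0 and 1 counts in the 2 libraries. Release M4 and a genome sequence were not used here. Hairpin sequences came from the M21 transcripts. A gene was marked as sharing sequence where its hairpin had a stretch of at least 20 nt in common with another, non-overlapping M21 hairpin. This applied to 929 genes, of which 70 (7.53%) were detected, against 235 of 965 others (24.4%). The sharing genes held 8.15% and 8.13% of the counts. Each gene was given at most 1 host, a gene other than miRNA that encloses its hairpin on the same strand. Protein-coding hosts were taken first, then the shortest. "Exon" means overlap with an exon of that host, and "intron" means no such overlap. "Intergenic" or "between genes" means that no such host was found, whatever lies on the other strand.

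Levels are own-strand counts per 1000000 own-strand counts (CPM), as mean and SD over the pups. Detection required at least 10 counts in each library. The floor is 3 counts. The pups were compared by a two-sided exact binomial test per detected gene against TMM effective library sizes from edgeR 4.0.16 (R 4.3.3), with Benjamini-Hochberg adjustment over 305 genes. A gene was called at an adjusted p under 0.05 and a ratio of at least 1.5. The design has a single group, so no contrast between conditions was fitted. The edgeR common dispersion came from an intercept-only model. DESeq2 1.42.0 gave alternative size factors. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

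Before the data were examined, 23 gene lists were fixed, 15 of them for cell types, together with 29 polycistronic clusters, the tests and the alternatives. Of the symbols fixed, 10 of 14 were analysed for let-7, 4 of 8 for leukocytes, 2 of 3 for smooth muscle and 47 of 55 for the Dlk1-Dio3 region. Some of the rest are alternative names of an analysed gene, such as Mir145. Others, such as Mirlet7e, Mirlet7f-1, Mir142, Mir376a and Mir409, are seen here only as reads opposite to another gene. Counts of members refer to those analysed. A list's share is the sum of its members' CPM. Its median log2(CPM + 1) was ranked among 10000 random lists of the same size. Its median pup ratio was ranked among 10000 random lists matched in 10 bins of mean CPM, with a two-sided p adjusted over the 22 lists that had a value. The genes named are the 20 most abundant, up to 4 detected members with the highest mean of each list (or the highest member if none was detected), the 5 largest called pup ratios each way among genes with a mean of at least 100 counts, and the highest and lowest member of each cluster. The rule also provided for genes other than miRNA, and there were none among the matched identifiers. Named outside this rule, after their values were seen, are Mir30c-2, Mir7083, Mir1a-1, Mir133a-1, Mir133a-2, Mir124a-1, Mir124a-2, Mir124a-3, Mir92-1, Mir19a, and the genes on either side of the opposite-strand reads.

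The test of pup differences was checked on simulated counts made from the real means and library sizes, with 200 genes changed 2-fold or 4-fold. These counts held counting noise only, with no variation between libraries. For the comparison of the pups, 302 simulated genes passed the filter. The exact binomial test recovered 93.9% of 66 genes changed 2-fold and 100% of 53 genes changed 4-fold, and called 0% of 183 unchanged genes. That 0% says little about false calls here, as the real libraries vary beyond counting noise. With a simulated coefficient of variation of 11.4% between libraries, edgeR returned 10.5%, and the binomial test called 5 of 309 unchanged genes. The ranking of lists was checked on independent random values instead of counts, so that check does not cover lists whose genes vary together. Of 100 random lists of 8 genes with no shift, 5 fell outside the central 95%, and 98 of 100 lists shifted by 0.5 on the log2 scale lay above it. Smaller shifts were not simulated.

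Alternatives covered the detection minimum (1 or 100 counts), counts without regard to strand, total-count scaling, DESeq2 size factors, edgeR dispersion as the error, lists without multi-locus symbols or without the most abundant gene, detected genes as the background, 5 bins, and each pup left out. Added after seeing the data were opposite-strand counts credited to the overlapping gene, the striated muscle list without Mir206, the squamous list without Mir203, and lists without sequence-sharing genes.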

Results

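MicroRNA sequencing, which reads the RNA molecules shorter than about 30 nucleotides in a tissue, was carried out on stomach tissue from newborn (postnatal day 0) mice of the B6NCrl strain. The series holds 2 libraries, each from the stomach of a different pup of 1 dam, and the sex of the pups was not collected. They form 1 group, so the data describe which miRNA genes the newborn stomach expresses and how closely 2 littermates resemble each other, with no contrast between conditions. Reads assigned to miRNA genes on the gene's own strand numbered 4463355 in pup 1 and 3454655 in pup 2. These made up 62.0% and 62.3% of all reads in the tables. A count of 0 allows a level of up to 0.672 counts per 1000000 own-strand counts (CPM) in pup 1 and 0.868 CPM in pup 2, a limit that covers counting error only. Of 1973 miRNA genes, 305 were detected with at least 10 counts in each library, and 1320 had no count in either. Means below are over the pups, with their SD and n = 2.

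Among own-strand counts, a single miRNA gene led by far. Reads that mapped to several places, 26.0% of all reads in pup 1 and 25.7% in pup 2, stay outside this ranking. Mir143, a smooth muscle miRNA gene, held 24.2% ± 1.23 (SD, n = 2) of all own-strand counts, at 241858 ± 12311 CPM. It was followed by Mir203, a regulator of squamous epithelial differentiation, at 95385 ± 1150 CPM, and Mir99a at 63047 ± 1872 CPM. The gap between each of these and the next was larger than the SD of either gene. Mirlet7g (42007 ± 2018 CPM), the endothelial gene Mir126a (35026 ± 844 CPM), Mir21a (31266 ± 1682 CPM) and the epithelial gene Mir429 (29821 ± 287 CPM) came next. Mirlet7i and Mir26b, at 28544 ± 539 and 28538 ± 463 CPM, differed by less than the spread between pups. The 10 most abundant genes held 62.1% ± 1.56 of the counts, and the 20 most abundant held 77.5% ± 0.727. The lower part of the top 20 ran from Mir23a (25370 ± 1203 CPM), Mir23b (22885 ± 900 CPM) and Mir335 (19056 ± 1183 CPM) down to Mir322 (10751 ± 675 CPM).

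Mir143 (ENSMUSG00000065445.2) lies on the minus strand of chromosome 18 at 61649196 to 61649258 (GRCm38), between genes, and its 63-nt annotated hairpin reads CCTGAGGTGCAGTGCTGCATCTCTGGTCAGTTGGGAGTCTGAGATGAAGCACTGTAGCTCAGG. Mir203 (ENSMUSG00000065574.1) is also intergenic, on the plus strand of chromosome 12 at 112130880 to 112130955, with the hairpin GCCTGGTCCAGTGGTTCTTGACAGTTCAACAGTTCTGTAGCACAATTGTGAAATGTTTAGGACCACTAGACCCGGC. Mir99a (ENSMUSG00000065530.1) sits in an intron of its host RNA Mir99ahg on chromosome 16 at 77598936 to 77599000. Of the 20 most abundant genes, 9 lay in introns of their host gene, 5 overlapped an exon of their host and 6 had no host on their strand. Mir335 lies in an intron of the imprinted gene Mest, and Mir126a overlaps an exon of the endothelial gene Egfl7. Of these 20, Mir23a and Mir23b share a stretch of at least 20 nt with another annotated hairpin, so some of their reads may be counted elsewhere or nowhere.

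**Figure D1:**
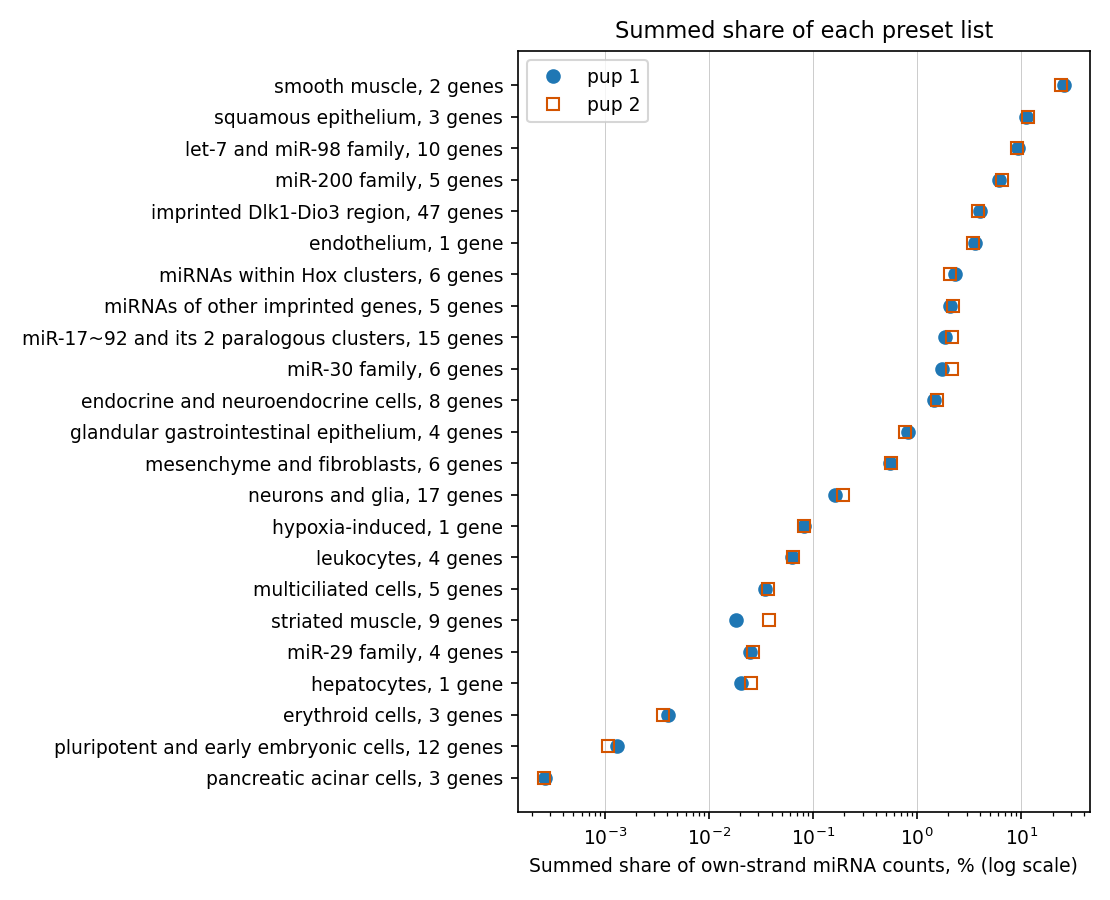
Share of own-strand miRNA counts (%, log axis) held by each of the 23 gene lists in pup 1 (filled circles) and pup 2 (open squares), with the number of member genes analysed. Smooth muscle is highest at 24.8% on average and pancreatic acinar cells are lowest at 0.000265%.

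The smooth muscle list held the largest share of any list, through 1 gene. Counts from whole stomach tissue do not tell which cells the reads of Mir143 came from. The smooth muscle list, Mir143 and Mir145a, held 24.8% ± 1.21 of the counts. Mir145a, transcribed together with Mir143, reached 5703 ± 221 CPM, so the list rests on Mir143. Without that gene in list and total it held 0.752%, below the 15.04% of squamous and the 1.045% of glandular epithelium on the same total, so its place as the highest list ended. The smooth muscle share exceeded the squamous epithelial share by 1.12 ± 0.115 on the log2 scale, a ratio of 2.17. Mir126a, the 1 endothelial gene analysed, held 3.50% ± 0.0844. The list for mesenchyme and fibroblasts had 6 of 6 members detected and held 0.555% ± 0.00409, led by Mir214 (3615 ± 88.7 CPM) and Mir140 (1273 ± 52.0 CPM), a gene active in cartilage and mesenchyme. Its members Mir199b (312 ± 19.5 CPM) and Mir199a-2 (67.8 ± 13.5 CPM) share a stretch of at least 20 nt with another hairpin, and reads of such genes can be missing from these counts.

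Epithelial miRNA genes were detected for both linings of the mouse stomach, the squamous forestomach and the glandular part. The squamous list had 3 of 3 members detected and held 11.4% ± 0.349 of the counts, with Mir205, a miRNA of stratified epithelia, at 16794 ± 2152 CPM and Mir31 at 1868 ± 184 CPM beside Mir203. The miR-200 family, which marks epithelium in general, had 5 of 5 members detected and held 6.36% ± 0.346. Its levels ran from Mir429 through Mir200c (15111 ± 2193 CPM), Mir200b (13479 ± 953 CPM) and Mir141 (3006 ± 379 CPM) to Mir200a (2159 ± 220 CPM). The list for glandular gastrointestinal epithelium, Mir192, Mir215, Mir194-1 and Mir194-2, had 4 of 4 members detected and held 0.792% ± 0.0330. Mir215 stood at 3799 ± 491 CPM and Mir192 at 2692 ± 131 CPM, whereas Mir194-1 (499 ± 75.6 CPM) and Mir194-2 (933 ± 216 CPM) share a stretch with another hairpin. The glandular share can therefore be understated. No squamous member shares a stretch, so the ratios of squamous to glandular share that follow can be overstated, which their SD does not cover. The squamous share exceeded the glandular share 14.4-fold, by 3.85 ± 0.104 on the log2 scale, with Mir203 making up 83.6% of the squamous share. Without Mir203, an alternative chosen after seeing the data, the squamous list held 1.87% and exceeded the glandular share 2.35-fold, by 1.23 ± 0.241 on the log2 scale. Endocrine and neuroendocrine genes had 8 of 8 members detected and held 1.51% ± 0.0809. Mir375, a miRNA of islet and gut endocrine cells, led that list at 7417 ± 372 CPM, followed by Mir182 at 3816 ± 958 CPM, Mir183 at 1966 ± 63.2 CPM and Mir96 at 1371 ± 206 CPM.

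The lists for other cell types each held a smaller share than those above. The neural list had 11 of 17 members detected and held 0.180% ± 0.0211, most of it from Mir137 (1220 ± 176 CPM), with Mir132 at 208 ± 7.07 CPM and Mir338 at 107 ± 8.13 CPM. The mesenchymal share exceeded the neural share 3.10-fold, and 13 of the 17 neural members share a stretch with another hairpin, so that the neural share can be understated. Mir124a-1, Mir124a-2 and Mir124a-3 had no count, and as each shares a stretch with other hairpins their level cannot be read from these counts. Leukocyte genes, with 4 members analysed, held 0.0636% ± 0.00161, led by the myeloid gene Mir223 (470 ± 15.4 CPM), with Mir146, which shares a stretch with another hairpin, at 72.6 ± 13.6 CPM. Crediting the reads counted opposite to Mir142b to the leukocyte gene Mir142, an alternative chosen after seeing the data, gave a leukocyte share of 0.109% of the counts on both strands. Without that credit the leukocyte share of the same total was 0.0622%. Multiciliated cell genes had 3 of 5 members detected and held 0.0356% ± 0.00151, with Mir34c at 206 ± 18.5 CPM and Mir449a at 645 counts in pup 1 and 476 in pup 2. The hepatocyte gene Mir122 stood at 230 ± 35.2 CPM and held 0.0230% ± 0.00352. Erythroid genes held 0.00386% ± 0.000304, with Mir451a at 92 and 67 counts and Mir144 at 85 and 53 counts. The pluripotency list had 1 of 12 members detected, Mir302a at 4.73 ± 0.674 CPM, and held 0.00120% ± 0.000177. Mir302a shares a stretch with another hairpin, and without sequence-sharing genes, the setting added after seeing the data, the list held 0.000417%. None of the 3 pancreatic acinar genes passed the detection minimum in both libraries, and their highest member, Mir217, stood at 1.28 ± 0.231 CPM.

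Striated muscle genes held 0.0279% ± 0.0135 of the counts, the widest spread between pups relative to the mean among the 23 lists. The share was 0.0184% in pup 1 (exact 95% interval 0.0172% to 0.0197%) and 0.0375% in pup 2 (0.0354% to 0.0396%). Of 9 members, 3 were detected: Mir206, a skeletal muscle miRNA, at 181 ± 118 CPM, Mir208b, in an intron of the slow myosin gene Myh7, at 88.2 ± 13.6 CPM, and Mir133b at 4.22 ± 0.582 CPM. Mir1a-1 had 1 count in pup 1 and none in pup 2, and Mir133a-1 and Mir133a-2 had none. Each of these 3 shares a stretch with other hairpins, as does Mir133b, so neither their levels nor that of Mir133b can be read from these counts. Without Mir206, an alternative chosen after seeing the data, the list held 0.00984%.

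Across the 15 cell type lists, 103 of 105 pairs had a mean log2 ratio larger than its SD over the pups. The exceptions were striated muscle against multiciliated cells (0.44 ± 0.66 for multiciliated over striated muscle) and striated muscle against hepatocytes (0.20 ± 0.50). With 2 libraries no exact permutation test can give a p under 0.5, so these ratios are set against the SD only. The lists differ in their number of members, so the ratios compare summed counts and do not measure amounts of cell types. The median member lay above the central 95% of random lists drawn from all miRNA genes for 17 of 23 lists. Set against detected genes only, this held for 5 lists.

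**Figure D2:**
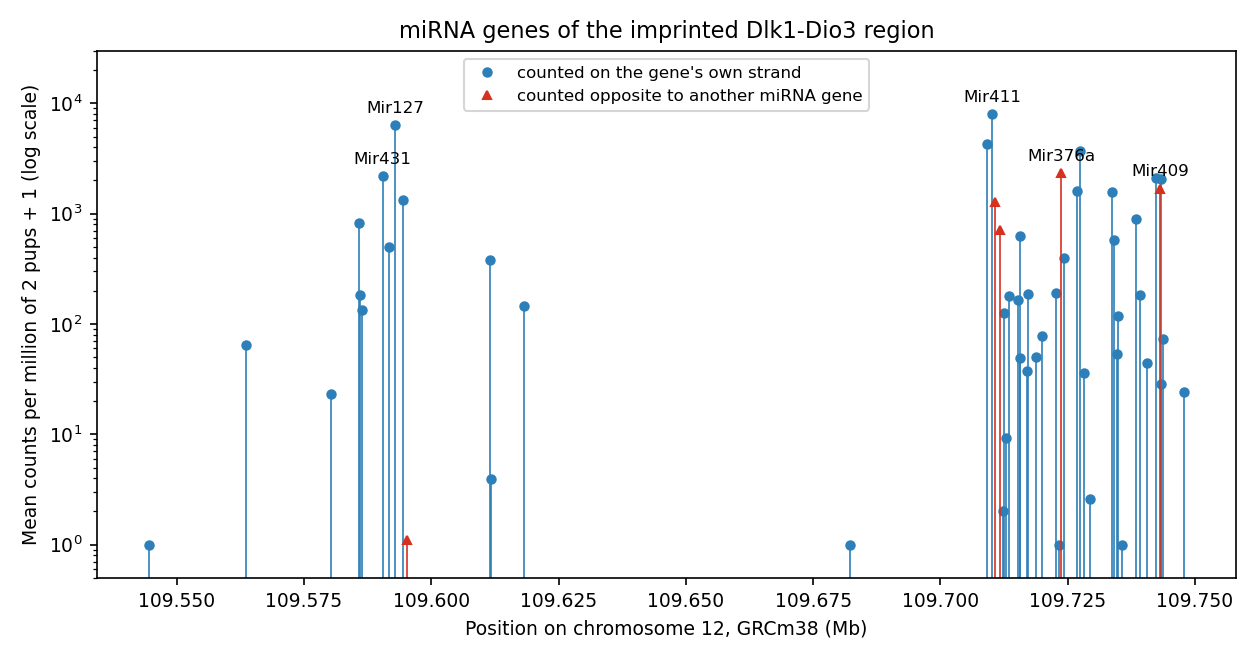
Mean CPM plus 1 over 2 pups (log axis) of miRNA genes along the imprinted Dlk1-Dio3 region of chromosome 12 (GRCm38, Mb). Circles are counts on the gene's own strand and triangles are counts on the strand opposite to another tabled miRNA gene; Mir411 is highest at 7979 CPM and Mir127 follows at 6323 CPM.

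Imprinted miRNA genes were widely detected. In the imprinted Dlk1-Dio3 region on chromosome 12, between 109544541 and 109747960, 41 of 47 analysed members were detected, and together the members held 3.94% ± 0.163 of the counts. Mir411 (7979 ± 399 CPM), Mir127 (6323 ± 4.12 CPM), Mir379 (4247 ± 199 CPM) and Mir487b (3668 ± 317 CPM) were the highest, of which Mir411 and Mir487b share a stretch with another hairpin. Without sequence-sharing genes, a setting chosen after seeing the data, the region held 2.76%. The miRNA genes of other imprinted loci held 2.15% ± 0.118, of which Mir335 made up 88.5%, with Mir296 at 1001 ± 61.3 CPM, Mir298 at 657 ± 11.4 CPM and Mir483, in an intron of Igf2, at 746 ± 66.4 CPM. The miR-210 gene Mir210, which hypoxia induces, stood at 815 ± 2.58 CPM and held 0.0815% ± 0.000258.

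The let-7 and miR-98 family had 10 of 10 analysed members detected and held 9.22% ± 0.0799, led by Mirlet7g and Mirlet7i, with Mirlet7d at 9937 ± 102 CPM and Mir98 at 4663 ± 31.2 CPM. Of its members, 5 share a stretch with another hairpin. Genes within the Hox clusters held 2.18% ± 0.171, with Mir10a at 18114 ± 1479 CPM, Mir10b, in an intron of Hoxd4, at 2957 ± 242 CPM and Mir615, in an intron of Hoxc5, at 714 ± 3.32 CPM. Mir196b reached 9.33 ± 4.00 CPM. The miR-17~92 cluster and its paralogs, which promote proliferation, had 13 of 15 members detected and held 2.01% ± 0.206, with Mir17 at 7327 ± 1042 CPM, Mir20a at 3448 ± 616 CPM, Mir93 at 3255 ± 397 CPM and Mir106b at 2955 ± 81.2 CPM. The miR-30 family held 1.95% ± 0.298, with Mir30e at 11215 ± 2008 CPM, Mir30d at 4076 ± 491 CPM and Mir30a at 3913 ± 459 CPM. The miR-29 family held 0.0259% ± 0.00128, with Mir29a at 143 ± 2.98 CPM and Mir29c at 114 ± 15.1 CPM. Of its 4 members, 3 share a stretch with another hairpin, Mir29c among them, and without such genes the family held 0.0143%.

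**Figure D3:**
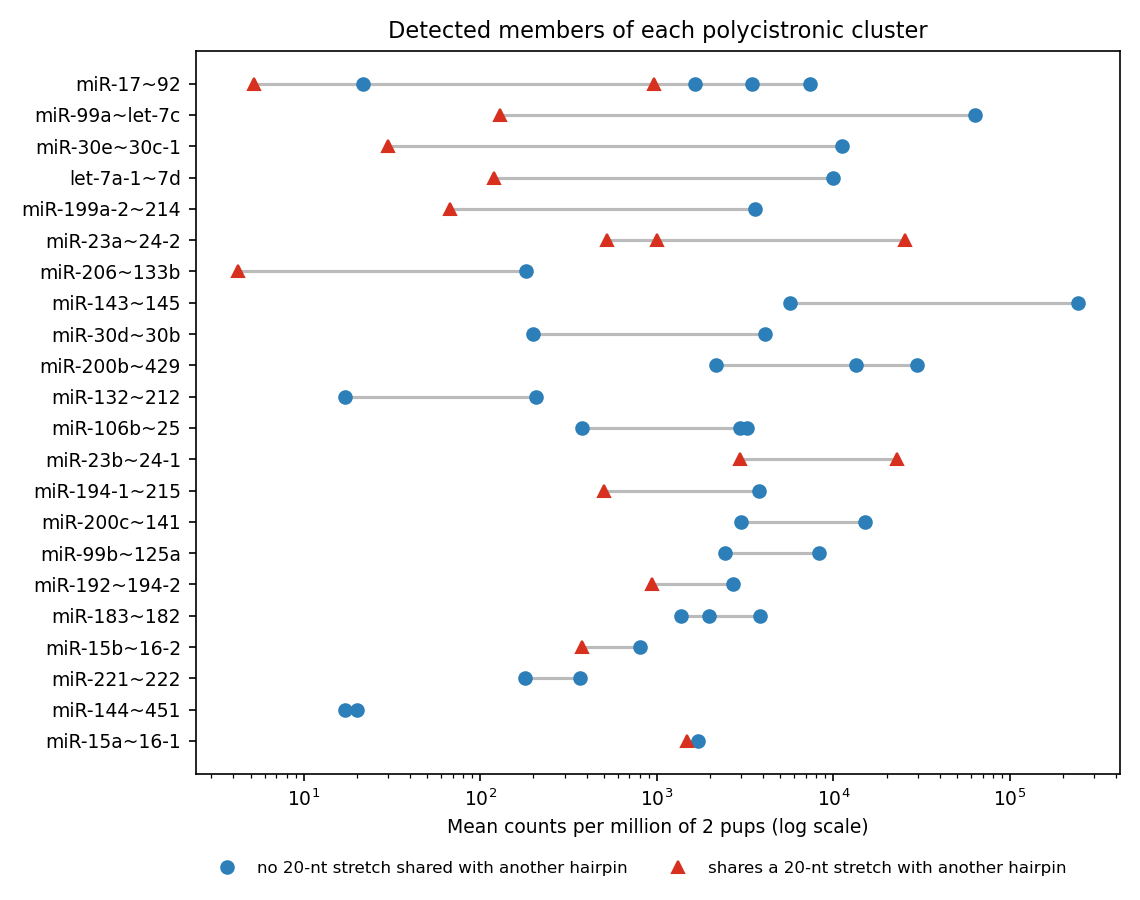
Mean CPM over 2 pups (log axis) of the detected members of 22 polycistronic clusters, ordered by the ratio of highest to lowest. Triangles mark genes that share a stretch of at least 20 nt with another annotated hairpin; Mir17 exceeds Mir19b-1 by 1401-fold, and Mir15a and Mir16-1 lie within 1.15-fold.

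Members of polycistronic clusters, which are cut from 1 primary transcript, differed widely in counts. Of 29 clusters fixed beforehand, 22 had at least 2 detected members. Their highest member exceeded the lowest by a median of 10.4-fold, and by over 2-fold in 20 of the 22. Mir143 exceeded its partner Mir145a 42.4-fold, or 5.41 ± 0.129 on the log2 scale, against a between-pup SD of 0.205 for detected genes. Mir429 exceeded Mir200a 13.8-fold, Mir200c exceeded Mir141 5.03-fold, Mir93 exceeded Mir25 8.65-fold and Mir30d exceeded Mir30b 20.5-fold, none of which shares a stretch with another hairpin. The largest ratios were those of Mir17 over Mir19b-1 (1401-fold), Mir99a over Mirlet7c-1 (484-fold) and Mir30e over Mir30c-1 (373-fold), where the lower member does share one. In 12 of the 22 clusters the lowest member was such a gene. Mir19a, which shares none and was named after its values were seen, stood at 21.6 ± 2.64 CPM in the cluster of Mir17. Mir451a over Mir144 (1.16-fold) and Mir15a over Mir16-1 (1.15-fold) were the clusters with ratios under 2.

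**Figure D4:**
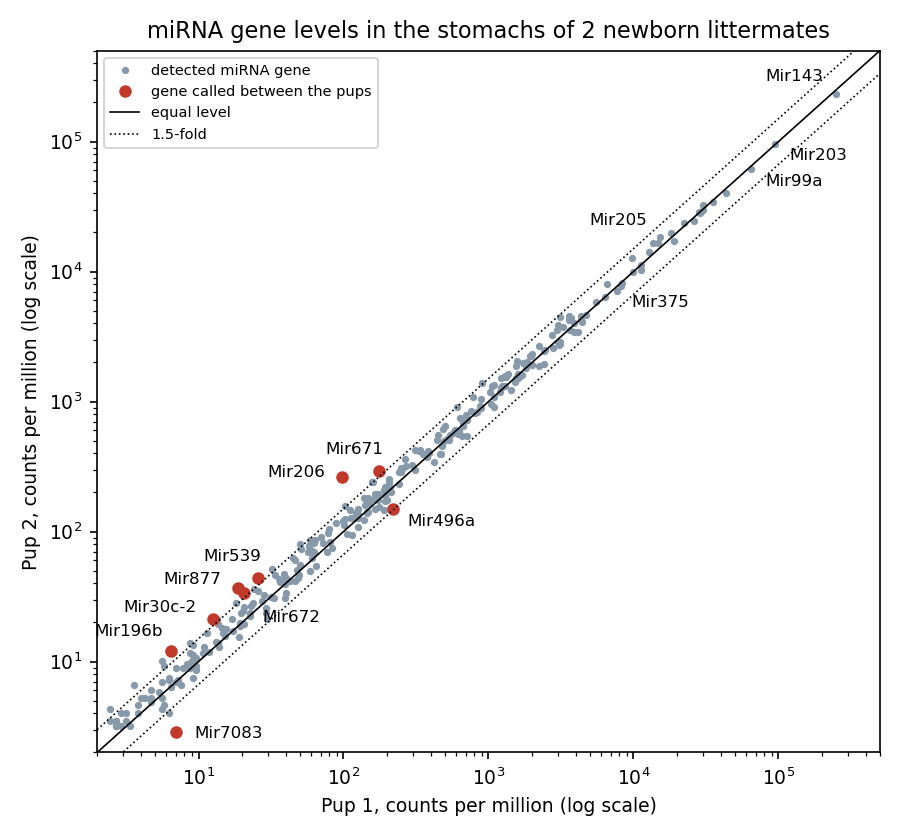
CPM of 305 detected miRNA genes in pup 1 (x axis, log) and pup 2 (y axis, log), with the line of equal level and dotted lines at 1.5-fold, before TMM scaling. Red points are the 9 genes called between the pups; Mir206 lies farthest from the line, with 435 counts in pup 1 and 914 in pup 2.

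The stomachs of the 2 pups had closely similar miRNA profiles. Across the 305 detected genes, log2 CPM correlated with a Pearson r of 0.997 and a Spearman rho of 0.996, values that describe agreement across genes, which are not independent replicates. The median absolute log2 ratio was 0.172 after TMM scaling, and 292 of 305 genes (95.7%) lay within 1.5-fold. Scaled by total counts alone, the median gene was lower in pup 1 by a log2 ratio of -0.13, so the ratios below are relative to TMM scaling, which leaves a median of -0.02. The counts differed by far more than sampling noise (chi-square of 18619 over 304 degrees of freedom), so these are not 1 library deposited again. The edgeR common dispersion corresponded to a coefficient of variation of 11.4% between pups.

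Mir206 was the gene with the clearest difference between the pups, at 435 counts in pup 1 and 914 in pup 2. Its log2 ratio of pup 1 over pup 2 was -1.34 (exact 95% interval -1.51 to -1.17; adjusted p = 3.7e-60, two-sided exact binomial test). Mir206 (ENSMUSG00000065559.1) lies on chromosome 1 at 20679010 to 20679082, plus strand, over an exon of Gm28653, and its hairpin reads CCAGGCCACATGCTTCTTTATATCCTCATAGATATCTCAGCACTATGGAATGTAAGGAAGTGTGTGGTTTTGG. In all, 7 genes were higher in pup 2 and 2 in pup 1. Besides Mir206, the named genes higher in pup 2 were Mir877 (log2 ratio -0.86), Mir539 (-0.68), Mir671 (-0.62), Mir672 (-0.61) and Mir196b (-0.80), with adjusted p from 5.0e-19 for Mir671 to 0.045 for Mir196b in the exact binomial test. The other was Mir30c-2 (-0.67), named after its values were seen. Higher in pup 1 were Mir496a (0.67), in the Dlk1-Dio3 region at 109739119 to 109739197, and Mir7083 with 31 against 10 counts, also named after its values were seen. This test compares these libraries and covers counting error only. With edgeR's common dispersion as the error, Mir206 alone was called (adjusted p = 3.1e-05), and 16 genes had an unadjusted p under 0.05. That dispersion comes from the same 2 libraries and gives no gene a spread of its own, so this p does not show that the difference exceeds the variation between pups. In simulated unchanged genes with that dispersion, the binomial test called 5 of 309, beside the 9 called here. Scaled by total counts, 15 genes were higher in pup 2 and 1 in pup 1, as Mir496a lost its call (log2 ratio 0.57), and with DESeq2 size factors the numbers were 6 and 4.

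Of the 22 lists with a detected member, the Dlk1-Dio3 list was the 1 whose median pup difference fell outside the central 95% of abundance-matched random lists. Its median log2 ratio of pup 1 over pup 2 was 0.11, at the percentile 99.4, with 29 of 41 members higher in pup 1 by value. Its two-sided p from random lists was 0.012, and 0.27 after adjustment over the 22 lists, so the difference did not pass adjustment. The check of this ranking did not cover lists whose genes vary together. Of the Dlk1-Dio3 members, 1 was called higher in pup 1 (Mir496a), 1 higher in pup 2 (Mir539) and 39 were not called, and 2 were called when p was adjusted over the list alone. The squamous, miR-200, glandular, endocrine, smooth muscle and endothelial lists held no gene called between the pups. In the striated muscle list 1 of 3 detected members was called, Mir206, and likewise 1 when adjusted over the list alone.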

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

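Each result here was singled out because reads lay in a count column that the report's comparisons do not use, the strand opposite to the annotated gene, above the limit that a count of 0 allows. The test of overlap was set before its result was seen.

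Reads on that strand lay at the positions of several well-known miRNA genes. Reads opposite to Gm25301 numbered 46914 in pup 1 and 30346 in pup 2, at the position of Mir378a on the other strand, a level of 9434 ± 1187 CPM of all gene counts (SD, n = 2). Opposite to Gm25927 there were 11777 and 10969 reads, at Mirlet7e. Opposite to Gm25252 there were 10579 and 8219, at Mir376a, and opposite to Gm24083 there were 10125 and 8638, at Mir191. Opposite to Gm24321 there were 7704 and 5893, at Mir409, and opposite to Mir299b 5949 and 4501, at Mir299a. Gm25750 had 3627 and 2236 opposite reads, at Mir380. Mir497b had 3540 and 2942, at Mir497, and Mir142b had 2120 and 1673, at the leukocyte gene Mir142. Gm24111 had 456 and 388, at Mirlet7f-1, and Mir3074-1 had 235 and 131, at Mir24-1.

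These 11 genes held 99.9% of all opposite-strand counts in each library. A candidate explanation is that the reads come from the miRNA gene on the other strand, and 99.96% of opposite-strand counts in the library with the lower share lay in genes overlapping an annotated miRNA gene on that strand, against 1.62% of tabled genes with such a partner. A loss of strand during library making would place opposite reads at abundant genes without a partner as well, and those held the remainder. Of the 32 tabled genes with such a partner, 0 had the partner itself among the genes analysed here, so the reads could not be set beside counts of the partners. No biological explanation was tested.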

How the results depend on the processing

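Tests with opposite-strand counts added, without Mir206, without Mir203 and without sequence-sharing genes were chosen after seeing the data. With at least 1 count in each library, 508 genes were detected, Spearman's rho was 0.9726 and the median absolute log2 ratio 0.2417, as genes of few counts enter. Genes called higher in pup 1 numbered 1 with total-count scaling, 4 with DESeq2 size factors, 1 with at least 100 counts in each library and 0 with edgeR common dispersion as the error, and those higher in pup 2 numbered 15 with total-count scaling and 1 with edgeR common dispersion as the error. With the total without the most abundant gene, which raises every other share, the shares were 8.383% for the miR-200 family, 15.04% for squamous epithelium, 1.045% for glandular epithelium, 1.991% for endocrine cells, 4.621% for endothelium and 0.7522% for smooth muscle, which loses Mir143 and so fell from above to below each of these other shares. Without Mir203 the squamous share was 1.866%. The glandular share was 0.649% both without multi-locus symbols and without sequence-sharing genes, which drops both Mir194 genes. Against detected genes only, 5 lists lay above the central 95% of random lists, because the background then leaves out genes at 0. Mir877, Mir539, Mir671, Mir672 and Mir496a lost their call with edgeR common dispersion as the error, and Mir496a also with total-count scaling. Counts without regard to strand lowered 8 levels or shares by more than 1 SD, as the total grows. Leaving out 1 pup moved no level, share or cluster ratio that has an SD over the pups by more than that SD, but with 2 pups this is fixed by construction and says nothing about stability; the share of the 10 most abundant genes ranged from 60.98% to 63.19% and the median cluster ratio from 10.38 to 10.82. DESeq2 size factors shift every gene by 1 amount, so the lists' pup percentiles cannot move and the setting tests nothing there. Depth limits the lowest lists: genes below 10 counts in a library entered neither the main comparison of the pups nor the pup ratios of the lists.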

Other observations

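The Mir206 test below, and the test of clusters without sequence-sharing members, were chosen after the result was seen; the other tests were set before.

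Reads on the opposite strand lay at further imprinted miRNA genes in the Dlk1-Dio3 region, which are their candidate source. Mir376a stood at 2322 ± 7.93 CPM, Mir409 at 1678 ± 12.7 CPM, Mir299a at 1289 ± 19.8 CPM and Mir380 at 714 ± 114 CPM of all gene counts (SD, n = 2), whereas Mir136, in the same region, stood at 0.109 CPM. With opposite-strand counts credited to the overlapping gene, the region's share was 4.455% of the counts on both strands, against 3.855% without that credit. For the let-7 family these shares were 9.307% and 9.012%. The shares of 3.94% and 9.22% given above are of own-strand counts, a smaller total.

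For the differing counts of members of 1 polycistronic cluster, one hypothesis is that reads of mature sequences present at several loci were left out of the gene counts. Of 12 sequence-sharing members in 11 clusters, 10 were lower than the mean of their partners by more than the between-pup SD of 0.205, while Mir16-1 differed by less, as did Mir92-1, whose partners include Mir19a at 21.6 CPM, which shares no stretch. Over the 12, there was a median log2 difference of -5.42 (quartiles -6.60 and -1.42; one-sided exact permutation p = 0.011 over 15360 placements of the marks), in line with that hypothesis. Sharing between annotated hairpins leaves unaccounted Mir19a and the 10 clusters whose detected members have no such stretch, where the highest exceeded the lowest by a median of 6.84-fold and by over 2-fold in 9. For these, copies of the sequence outside the annotated hairpins and differences in processing, stability or capture stay open, untested.

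Mir206 was higher in pup 2, with a log2 ratio of pup 1 over pup 2 of -1.34. More striated muscle RNA of 1 composition in that stomach could raise it. The other list members summed to 387 counts in pup 1 and 380 in pup 2. After scaling, their log2 ratio of pup 1 over pup 2 was -0.24 (exact 95% interval -0.45 to -0.03, counting error only). They were thus also higher in pup 2, but only 1.18-fold, which argues against that explanation for the full difference of Mir206. The sum of the other members is mostly Mir208b (351 and 338 counts), and the levels of Mir1a-1, Mir133a-1, Mir133a-2 and Mir133b cannot be read from these counts. Muscle of another makeup, carrying Mir206 with little Mir208b, stays open, as does a difference between the pups themselves.

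Neighbouring miRNA genes were tested for a shared pup difference: over 98 pairs within 10 kb on 1 strand, the median absolute difference of their log2 ratios was 0.203, against 0.243 in abundance-matched shuffles, of which 93.42% were larger (one-sided permutation p = 0.066). Outside the Dlk1-Dio3 list, 90.9% of shuffles were larger over 61 pairs. The bound set beforehand counted any share under 95% against sharing, and by that bound the result went against it. The bound left no range for an undecided result, although the observed median lay below that of the shuffles, so after the result was seen it was read as open. Sharing and its absence cannot be told apart here with 98 pairs.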
